A study of Mus musculus with 4 samples.

How the data were processed

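RNA-seq libraries were made from total RNA of mouse Th2 cells with the TruSeq Stranded mRNA kit, per the labels' protocols. The 4 libraries form 2 groups of 2, PBS and 10 µM dopamine, as the sample titles give them. FastQC 0.11.2, TopHat2 2.0.13, HTSeq 0.6, DESeq2 (no version), R 3.6.2 and the mm10 build are named per the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not have been told apart.

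The file used was 1 table of 26207 genes. Per the file headers it holds the authors' DESeq2 comparison of dopamine with PBS, with a deposited log2 fold change and its standard error on the log2 scale, a Wald score, and raw and adjusted p-values. Its 4 library columns are a signal that the authors made by dividing each gene's read count by 1 size factor per library (normalized counts), per the file headers and the values. The values are whole multiples of what 1 read is worth in each column, and 100% of them came out whole within a tolerance of 0.01, so reads could be recovered. The size factors that follow are 0.589, 1.31, 1.30 and 1.03 for PBS A, PBS B, dopamine A and dopamine B. The columns carry the numbers 2 and 3 where the titles have replicates 1 and 2, so each column was matched to its group only, and A and B only name columns. There were 0 columns of other samples. No gene had fewer than 8 recovered reads in total, and 26 gene names had been turned into dates. The authors' adjusted p-values were given for 12997 genes and were NA for 13210.

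Depth was 5717408 to 14167357 recovered reads assigned to genes. A read in PBS A was worth 1.70 normalized counts and a read in the other libraries 0.766 to 0.971, so values of a few normalized counts rest on a few reads. Libraries of a group differed by more than sampling noise. A chi-square over genes gave 2.64 per degree of freedom for PBS and 3.98 for dopamine, so neither pair looks like a single library deposited under both names.

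Before the data were examined, the tests, the rule for named genes, 46 gene lists and the main alternatives were fixed. The lists were written from memory without a pathway database, so their names do not stand for curated sets. The plan named edgeR for read counts. Because the deposited values are normalized, the test planned for that case was used: limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(value + 1), no filter, 2-sided, Benjamini-Hochberg at 0.05. A fold change on this scale understates the change of genes with low values. Gene lists with at least 5 tested members were tested with camera (limma) against all other genes with a preset correlation of 0.01, adjusted over 34 program lists and separately over 12 lists of markers of other cell types. Camera with an estimated correlation and fry were run beside it. None of the list calls held with an estimated correlation: camera then called 0 of 34 program lists and 0 of 12 marker lists, with 5 and 2 at an unadjusted p under 0.05. That setting takes its degrees of freedom from the 4 libraries, so it had little power. Its lowest unadjusted p was 0.0156, for heat shock, and ribosomal proteins, with 68 of 77 higher and 0 lower, had 0.107. Failing it therefore does not show that a list was unchanged. Fry called 14 program lists and 5 marker lists. The test fry makes does not compare a list with other genes.

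Named genes are those with the 12 largest log2 fold changes in each direction among genes past the threshold, with both dopamine libraries on the same side of both PBS libraries and at least 5 CPM in the higher group. Predicted gene models and immunoglobulin or T cell receptor segments were left out of that part. Up to 4 members with the smallest p per list were added, and Il4, Il5, Il13, Gata3, Il1rl1, Il2ra, Cd69, Itgae, S1pr1, Klf2 and Drd1 to Drd5 were named whatever their p, as were the helper T cell markers Cd3d, Cd3e, Cd3g, Cd4, Trac and Trbc2. Some genes that the rule names are not reported here.

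The recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM and filterByExpr) as an added alternative. It called 5219 of 15329 genes, of which 4345 were also called by limma in the same direction. DESeq2 1.42.0 on the recovered reads called 3261. Other alternatives were edgeR with DESeq2 size factors, upper-quartile scaling or no filter, limma-voom, a pseudocount of 0.1, a filter at a mean of 5 CPM, a minimum change of 2-fold, and leaving out each library. Added after the data were seen were TMM scaling and scaling on genes with a mean of at least 100 in limma, a background of such genes for camera, the number in the column name as a block, and a loess correction for GC content and length over 11407 genes with a mean of at least 20. GENCODE M21 gave a single location for 24693 symbols and length and GC content for 24744.

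Both tests were checked on simulated reads for this comparison, drawn for 26207 genes with 100 genes changed by 2-fold and 100 by 4-fold. Limma recovered 95% and 100% of these, with 8 of 25986 unchanged genes called, and edgeR recovered 97% and 100% with 9. The changed genes were drawn from those with a mean of at least 20, and every gene was given the same dispersion. The data hold 14596 genes under that mean and many more calls, so these rates need not hold for them. Camera, run on the same reads with the glycolysis list also raised, called 3 of 46 lists, glycolysis among them. Python 3.11.15 and matplotlib 3.10.9 were used for reading the table and for plots.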

Results

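The data were 4 bulk RNA-seq libraries of mouse T helper 2 (Th2) cells with spleen as the stated source, 2 given phosphate-buffered saline (PBS) and 2 given 10 µM dopamine. Th2 cells are CD4 helper T cells known for making the type 2 cytokines IL-4, IL-5 and IL-13. The study's title concerns sympathetic nerves in the lung and Th2 resident memory cells, and the comparison asks which transcripts differ when Th2 cells meet dopamine, a catecholamine that sympathetic nerves make. The recovered reads assigned to genes numbered 5717408 and 13241168 in the PBS libraries, here called PBS A and PBS B, and 14167357 and 11492182 in dopamine A and dopamine B. Values are the authors' normalized read counts, given as mean ± SD of n = 2 libraries per group. Log2 fold changes are dopamine minus PBS on the log2(value + 1) scale with their standard error (SE), and adjusted p-values are limma's with Benjamini-Hochberg adjustment over 26207 genes. The labels do not state whether libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. Limma also draws each gene's variance toward that of genes of like abundance. It did so with 42.4 prior degrees of freedom, far more than 4 libraries give a gene. The p-values therefore rest mostly on this pooled spread rather than on that of the gene itself. Locations are from GENCODE M21 on the mm10 build.

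Dopamine libraries held more transcript of granzymes, perforin, type 2 cytokines, Csf2 and the chemokines Ccl3 and Ccl4. They held less of the egress receptor S1pr1, of most interferon-stimulated genes tested and of basophil, platelet and red cell transcripts. The largest rise was in Gzmb, which encodes granzyme B, a protease of cytotoxic granules. It lies on chromosome 14 from 56258838 to 56262260 and went from 482 ± 30.4 to 7514 ± 330, a log2 fold change of 3.96 (SE 0.07, adjusted p = 1.33e-37). The largest fall was in H2-Q2, an MHC class I gene on chromosome 17 from 35342242 to 35346762, from 238 ± 14.6 to 18.5 ± 5.52, a log2 fold change of -3.65 (SE 0.21, adjusted p = 2.26e-18).

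Across the genome 5577 of 26207 genes passed an adjusted p of 0.05, 3743 higher and 1834 lower with dopamine, so 67.1% of calls were higher. Without PBS A, the shallowest library, 2914 passed (2152 higher), and without dopamine B 3276 passed (2242 higher). The share of higher calls moved with the scaling and the genes tested. It was 53.5% with edgeR's TMM on 15329 genes, 39% with upper-quartile scaling in edgeR, 36.2% when the libraries were rescaled on genes with a mean of at least 100, and 81.3% when only genes of at least 5 CPM (reads scaled to a common library total) were tested. Genes with a mean of at least 100 had a median log2 fold change of 0.198 in the authors' scaling and 0.003 after that rescaling, which also took the median of all genes from -0.081 to -0.256. A log2 fold change below about 0.198 in an abundant gene is therefore no larger than the shift between these scalings. Of the 4149 genes with a mean over 500, 2020 were called higher and 347 lower. Of the 4343 with a mean of 100 to 500, 1302 were called higher and 324 lower. Counts of list members that rose are to be read against these shares. In the authors' deposited table, 3261 genes had an adjusted p below 0.05, and each of these was also called here in the same direction.

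Among the 12 largest rises, Gzma, which encodes granzyme A, went from 52.9 ± 4.42 to 641 ± 70.1 (log2 fold change 3.57) and Gzmc from 14.2 ± 3.89 to 146 ± 42.0 (3.27). Il24, a cytokine of the IL-10 family, went from 15.6 ± 2.85 to 157 ± 7.20 (3.26). Csf2, which encodes GM-CSF, went from 13.8 ± 2.14 to 108 ± 0.703 (2.90). The chemokine genes Ccl4 (log2 fold change 2.81) and Ccl3 (2.64) rose together, and they are neighbours on chromosome 11. The others were Lancl3 (2.79), the gap junction gene Gja1 (2.72), the caveola gene Cavin3 (2.71), Tnfrsf8 encoding CD30 (2.31) and Prf1 encoding perforin (2.28). The adjusted p of these 12 genes was at most 2.08e-10. Reads of granzyme family members and of MHC class I genes can be shared between near-identical copies, so the split between members, H2-Q2 included, is uncertain.

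Among the 12 largest falls, Drc1, a gene of the ciliary dynein regulatory complex on chromosome 5 from 30281388 to 30366695, went from 439 ± 34.1 to 38.7 ± 5.66 (log2 fold change -3.47, adjusted p = 4.16e-22). Ppbp, a platelet chemokine gene, went from 446 ± 51.8 to 60.8 ± 3.54 (-2.85), Car1, a carbonic anhydrase of red cells, from 272 ± 60.2 to 46.6 ± 8.26 (-2.51), and Mcpt8, a basophil protease gene, from 545 ± 55.1 to 122 ± 13.1 (-2.15). Ccr9, the chemokine receptor of gut homing, went from 71.1 ± 6.79 to 12.4 ± 4.44 (-2.47). The log2 fold change was -2.58 for Gcsam, -2.49 for Stc1, -2.44 for Dapl1, -2.37 for Serpinb10, -2.36 for Nipal1 and -2.33 for Ifit1bl1. The adjusted p of these 12 genes was at most 4.55e-07.

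**Figure D1:**
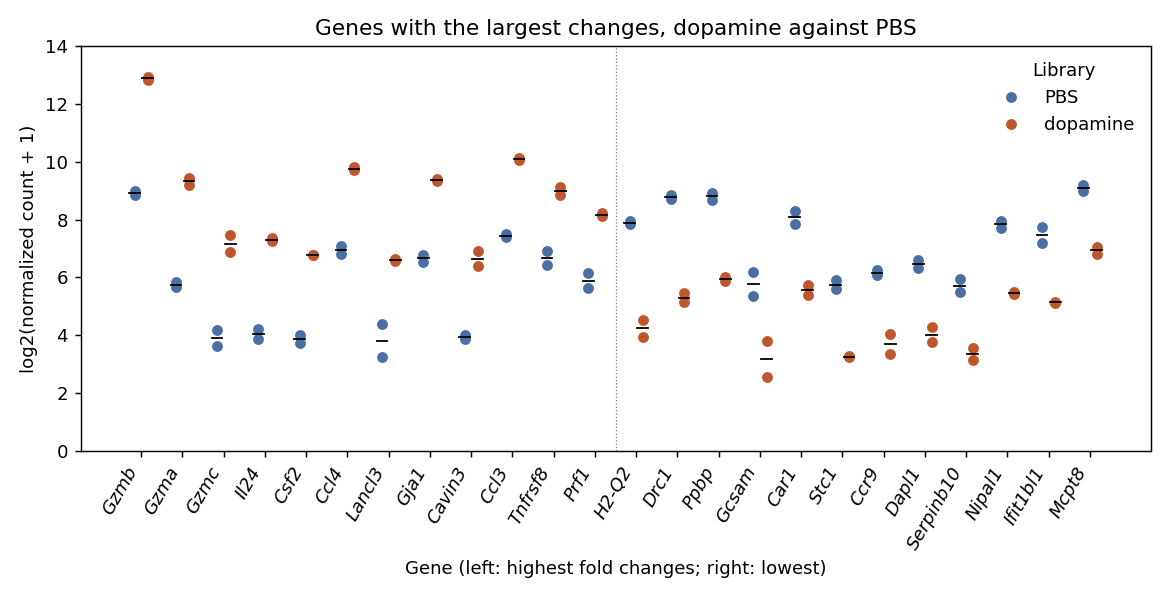
Normalized counts on a log2(value + 1) axis for the 12 genes with the largest rise (left of the dotted line) and the 12 with the largest fall (right). Each point is 1 library, blue for PBS and orange for dopamine, and the short bar is the mean of the 2 libraries. In each of these genes both dopamine libraries lie on the same side of both PBS libraries, as the rule for naming them required.

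Type 2 cytokine transcripts rose. Il4 went from 165 ± 19.4 to 754 ± 42.7 (log2 fold change 2.19, SE 0.11, adjusted p = 3.82e-20), Il13 from 203 ± 10.3 to 620 ± 9.19 (1.61, SE 0.11, adjusted p = 7.14e-16) and Il5 from 17.6 ± 6.41 to 50.4 ± 1.48 (1.51, SE 0.30, adjusted p = 1.14e-04). The genes share a stretch of chromosome 11, with Il4 starting at 53602982, Il13 at 53631324 and Il5 at 53720794. Gata3, the lineage factor of Th2 cells, was 237 ± 8.70 with PBS and 224 ± 24.1 with dopamine (log2 fold change -0.09, 95% interval -0.34 to 0.17, adjusted p = 0.69). Il1rl1, encoding the IL-33 receptor, fell from 61.4 ± 17.2 to 31.6 ± 2.07 (-0.91, adjusted p = 0.00554), a call that did not hold without PBS B (log2 fold change -0.63) or in DESeq2 (-0.99). Of 35 Th2 effector genes tested, 16 rose and 5 fell (16 and 5 adjusted over the list alone), with Cyp11a1 up by 1.64 on the log2 scale. Camera's adjusted p for the list was 1.2e-05, against an adjusted p = 0.284 with an estimated correlation. The list call also ended when only genes of at least 5 CPM were tested (adjusted p = 0.0531) or on a background of genes with a mean of at least 100 (adjusted p = 0.18). When scaled on genes with a mean of at least 100, 12 rose and 5 fell, and the list median went from 0.308 to 0.13. Il4 and Il13 are also made by basophils and mast cells, whose markers moved the other way: 8 of 10 fell (median log2 fold change -1.63).

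Genes of the Th1 and cytotoxic programs rose alongside. Of 24 Th1 effector genes, 15 rose and 4 fell (15 and 5 adjusted over the list alone), with a median log2 fold change of 0.83. Il12rb1, a chain of the IL-12 receptor, went from 296 ± 33.7 to 1021 ± 68.1, and Havcr2, encoding the inhibitory receptor TIM-3, from 47.2 ± 0.585 to 231 ± 30.8. The list had a camera adjusted p of 1.37e-09, against an adjusted p = 0.284 with an estimated correlation. Of 22 cytotoxicity genes, 10 rose and 0 fell by limma over all genes (10 and 2 adjusted over the list alone), among them Srgn, the granule proteoglycan serglycin, with a log2 fold change of 0.77. With edgeR's TMM 10 rose and 2 fell. When scaled on genes with a mean of at least 100, 9 cytotoxicity genes rose and 3 fell, and 15 Th1 genes rose and 6 fell. The list's adjusted p by camera was 2.06e-09, against an adjusted p = 0.284 with an estimated correlation. On the list of CD8 T cell markers, 3 of 6 genes rose and 0 fell by limma (4 and 0 adjusted over the list alone). Cd8a was at 27.5 ± 4.29 and 109 ± 9.05, far below Cd4, and Eomes went from 136 ± 4.2 to 289 ± 9.1 (log2 fold change 1.08). Camera's adjusted p for that list was 9.7e-04, against an adjusted p = 0.294 with an estimated correlation. The remaining member that rose is Trgv2 (log2 fold change 2.98), a segment of the gamma chain of the T cell receptor. Of the members that rose, only Cd8a encodes a CD8 chain. Of 8 gamma-delta T cell markers 2 rose and 0 fell by limma (3 and 0 adjusted over the list alone, adjusted p = 0.274 by camera): Tcrg-C2 from 17.8 ± 1.29 to 89.0 ± 5.04 (2.26) and Tcrg-C4 (1.34). Cd8b1, a member of the CD8 list that encodes the other CD8 chain, was 73.5 ± 4.21 and 98.1 ± 6.77 (adjusted p = 0.106).

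Markers of helper T cells were abundant in both groups. Cd4 was 4253 ± 24.3 with PBS and 4668 ± 115 with dopamine (log2 fold change 0.13, adjusted p = 0.122), and Cd3e was 379 ± 48.7 and 445 ± 7.65 (0.24, adjusted p = 0.121). Cd3d (log2 fold change 0.25), Cd3g (0.24) and Trbc2 (0.24) passed the threshold, but not without PBS A (0.15, 0.19 and 0.19) or with upper-quartile scaling in edgeR, and Trbc2 turned to -0.084 after a correction for GC content and length. Trac fell from 5316 ± 200.2 to 4403 ± 230 (-0.27, adjusted p = 8.38e-04), a call that ended without PBS B (-0.23).

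Genes of T cell activation and IL-2 signalling rose. Of 36 T cell receptor activation genes, 24 rose and 4 fell (24 and 4 adjusted over the list alone), and camera's adjusted p was 1.95e-12, against an adjusted p = 0.284 with an estimated correlation. Il2 went from 59.8 ± 5.33 to 275 ± 24.1, and Irf4, a transcription factor induced by receptor signalling, from 7620 ± 142 to 14598 ± 943. Of 32 targets of IL-2 and STAT5, 22 rose and 2 fell (24 and 3 adjusted over the list alone), with adjusted p = 2.3e-15 by camera, against an adjusted p = 0.284 with an estimated correlation. Lists share members, so their counts are not independent. Irf4 is on both of these lists, and the IL-2 and STAT5 list shares Gzmb with the cytotoxicity list and Il13 with the Th2 list. Il2ra, the high-affinity IL-2 receptor chain, went from 1765 ± 67.4 to 2519 ± 83.9 (log2 fold change 0.51, adjusted p = 2.19e-07). Of 29 NF-kB targets, 20 rose and 2 fell (21 and 3 adjusted over the list alone), with Nfkb2 at a log2 fold change of 1.16 and Tnf at 0.92. For these targets camera gave an adjusted p of 1.5e-11, against an adjusted p = 0.284 with an estimated correlation. Of 22 immediate early genes, which also respond to cell handling, 12 rose and 2 fell (14 and 2 adjusted over the list alone), with Junb at 1.24. Their adjusted p by camera was 1.09e-05, against an adjusted p = 0.284 with an estimated correlation, with 0.0925 among genes of at least 5 CPM and 0.0531 on a background of genes with a mean of at least 100. When scaled on genes with a mean of at least 100, more members of these lists fell: 19 rose and 7 fell for receptor activation (19 and 8 with upper-quartile scaling), 19 and 4 for IL-2 and STAT5, 18 and 5 for NF-kB and 9 and 4 for immediate early genes. The medians of these lists went from 0.495, 0.504, 0.631 and 0.415 to 0.301, 0.309, 0.436 and 0.22.

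The title's theme of tissue residency was addressed with lists for residency and for egress. S1pr1, the receptor that guides T cells out of tissues, fell from 1027 ± 16.3 to 344 ± 32.6 (log2 fold change -1.58, SE 0.10, adjusted p = 1.67e-17). Klf2, the transcription factor known to drive S1pr1, fell from 117 ± 9.69 to 60.7 ± 6.18 (-0.94, adjusted p = 1.08e-04). Il7r, encoding a chain of the IL-7 receptor, rose from 123 ± 27.8 to 379 ± 35.8. Of 26 egress and circulation genes, 12 fell and 5 rose (13 and 5 adjusted over the list alone). By camera the adjusted p was 2.88e-04, against an adjusted p = 0.39 with an estimated correlation; the number that rose was 3 without PBS A, and 3 rose and 15 fell when scaled on genes with a mean of at least 100. Fry did not call the egress list (adjusted p = 0.0879). Residency markers went both ways: of 40 genes, 13 rose and 10 fell (14 and 10 adjusted over the list alone). The residency list did not pass camera (adjusted p = 0.151) but passed fry as higher (adjusted p = 0.0201). When scaled on genes with a mean of at least 100, 12 rose and 14 fell. Rgs1 (log2 fold change 1.59) and Rgs2 (1.61) rose and Icos (-1.35) fell. Cd69, a residency and activation marker, was 4391 ± 50.5 and 4164 ± 177 (-0.08, adjusted p = 0.417) and was called lower, at -0.18, with edgeR's TMM. Itgae, encoding CD103, was 30.6 ± 9.63 and 24.0 ± 0.978 (-0.30, 95% interval -0.93 to 0.32, adjusted p = 0.533). Of 36 chemokine receptor, integrin and adhesion genes, 11 fell and 7 rose (11 and 8 adjusted over the list alone, adjusted p = 0.123), with Itga6 at -1.12 and Itgb1 at 0.81. That list passed as lower among genes of at least 5 CPM (adjusted p = 0.0461), with size factors of DESeq2 (0.0331) or upper-quartile scaling (0.0471) on edgeR's values, against genes with a mean of at least 100 (0.0022) and without dopamine B (0.00455). Without PBS A 7 of its genes fell, and when scaled on genes with a mean of at least 100 7 rose and 16 fell.

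Dopamine receptor transcripts were near the limit of detection. Drd1 was 1.53 ± 2.17 with PBS and 1.93 ± 2.73 with dopamine, Drd2 was 2.93 ± 3.06 and 2.23 ± 0.969, and Drd3 was 3.78 ± 4.26 and 2.41 ± 2.04, values of a few reads per library at which no difference was detectable (adjusted p of at least 0.861). Drd4 and Drd5 were not among the 26207 genes with values, so they could not be tested. Of 23 genes for catecholamine receptors and handling, 2 fell and 0 rose by limma (2 and 0 adjusted over the list alone). These were Slc18a2, the vesicular monoamine transporter, from 247 ± 12.8 to 113 ± 15.7, and Slc22a3, an organic cation transporter, from 39.0 ± 9.68 to 13.4 ± 0.339. Camera's adjusted p for the list was 0.0436, against an adjusted p = 0.425 with an estimated correlation, and it did not hold with TMM scaling (0.0513), with scaling on genes of a mean of at least 100 (0.194), or on edgeR's values with size factors of DESeq2 (0.258) or upper-quartile scaling (0.388). The call ended without PBS A (adjusted p = 0.173), dopamine A (0.0558) or dopamine B (0.0827), as did that of Slc22a3 without PBS A (log2 fold change -1.21), where 1 member fell and 1 rose. Only 5 of the list's members had a mean of at least 20, with a median log2 fold change of 0.028, against -0.767 for all 23. Genes below that mean were lower in general. Slc18a2 stores amines in basophils and mast cells too, whose markers fell. Of 35 cAMP and CREB targets, 11 rose and 10 fell (12 and 10 adjusted over the list alone, adjusted p = 0.387), and 10 rose and 12 fell when scaled on genes with a mean of at least 100.

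Interferon-stimulated genes fell. Of 56 genes, 37 fell and 10 rose (38 and 10 adjusted over the list alone), with a median log2 fold change of -0.56. Ifit1 had a log2 fold change of -1.70 (SE 0.11), with Ifi213 going from 495 ± 80.7 to 116 ± 19.5 (-2.08) and Ifi208 from 738 ± 169 to 209 ± 43.6 (-1.81). Ly6a, encoding the surface protein Sca-1, rose from 3203 ± 210 to 7591 ± 513. With camera the adjusted p was 3.52e-15, against an adjusted p = 0.39 with an estimated correlation. Fry did not call the list (adjusted p = 0.0999). The number that rose was 5 without PBS A, 5 with upper-quartile scaling and 6 with scaling on genes of a mean of at least 100. Members of the Ifit and Ifi200 families have near-identical copies, so the split between them is uncertain.

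Redox, protein-folding and amino acid stress genes rose. Of 30 NRF2 targets, 19 rose and 3 fell (20 and 3 adjusted over the list alone). Txnrd1, encoding thioredoxin reductase, went from 598 ± 48.7 to 1579 ± 82.3 (log2 fold change 1.40), with Txn1 at 0.96 and Gsr at 0.84. Of 17 heat shock genes, 12 rose and 0 fell by limma (13 and 0 adjusted over the list alone), with Hsp90aa1 at 0.76. Of 23 unfolded protein response genes, 17 rose and 0 fell by limma (17 and 0 adjusted over the list alone), with the chaperone gene Hspa5 at 0.64. Of 32 integrated stress response genes, 24 rose and 1 fell (24 and 2 adjusted over the list alone), with Atf4 at 0.64; 14 rose and 5 fell when scaled on genes with a mean of at least 100. Under that scaling 16 NRF2 targets rose and 3 fell, 10 heat shock genes rose and 0 fell by limma, and 12 unfolded protein response genes rose and 1 fell. The medians of the 4 lists then went from 0.536, 0.421, 0.445 and 0.435 to 0.341, 0.226, 0.25 and 0.24. Camera's adjusted p was 9.31e-13 for NRF2, 9.86e-13 for heat shock, 7.35e-13 for the unfolded protein response and 4.28e-11 for the integrated stress response. With an estimated correlation each had an adjusted p = 0.284.

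Metabolic genes moved in different directions. Of 53 nuclear-encoded oxidative phosphorylation genes, 46 rose and 0 fell by limma (51 and 0 adjusted over the list alone), with Uqcrq at a log2 fold change of 0.87 and a list median of 0.39. Of 77 cytosolic ribosomal protein genes, 68 rose and 0 fell by limma (72 and 0 adjusted over the list alone), with Rplp2 at 0.90 and a median of 0.34. Transcripts of the mitochondrial genome fell: 8 of 12 lower and 0 higher by limma (8 and 0 adjusted over the list alone), with mt-Nd4 from 4195 ± 417 to 2126 ± 126. Of 22 glycolysis genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone), with the glucose transporter Slc2a3 from 1469 ± 5.56 to 513 ± 48.5. Of 27 hypoxia response genes, 14 fell and 3 rose (16 and 3 adjusted over the list alone), with Bnip3 at -1.46 and Bhlhe40 at 1.06. Of 25 cholesterol synthesis genes, 13 rose and 0 fell by limma (14 and 0 adjusted over the list alone), with Pmvk at 1.14. In this order camera's adjusted p was 1.61e-24, 1.19e-39, 8.54e-08, 3.38e-05, 1.3e-05 and 1.77e-06. With an estimated correlation the adjusted p was 0.39 for glycolysis and 0.284 for the others.

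The number of genes called in abundant groups moved with the scaling and with the libraries used. When scaled on genes with a mean of at least 100, 27 oxidative phosphorylation genes, 41 ribosomal protein genes and 9 cholesterol synthesis genes rose, while 2 ribosomal protein, 2 cholesterol synthesis and 17 glycolysis genes fell. The medians of the first 3 lists were then 0.194, 0.142 and 0.147, against 0.389, 0.338 and 0.342 in the authors' scaling. After a correction for GC content and length, 27 oxidative phosphorylation genes rose and 1 fell, and 26 ribosomal protein genes rose and 6 fell, with medians of 0.17 and 0.103. Without PBS A, with fewer samples, 29 oxidative phosphorylation, 41 ribosomal protein and 7 cholesterol synthesis genes rose, and 7 glycolysis, 4 mitochondrial and 10 hypoxia genes fell. In this order the medians were then 0.378, 0.273, 0.242, -0.212, -0.314 and -0.452, against 0.389, 0.338, 0.342, -0.22, -0.286 and -0.421 with all libraries. The cholesterol list no longer passed among genes of at least 5 CPM (adjusted p = 0.0766) or on a background of genes with a mean of at least 100 (0.0645).

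**Figure D2:**
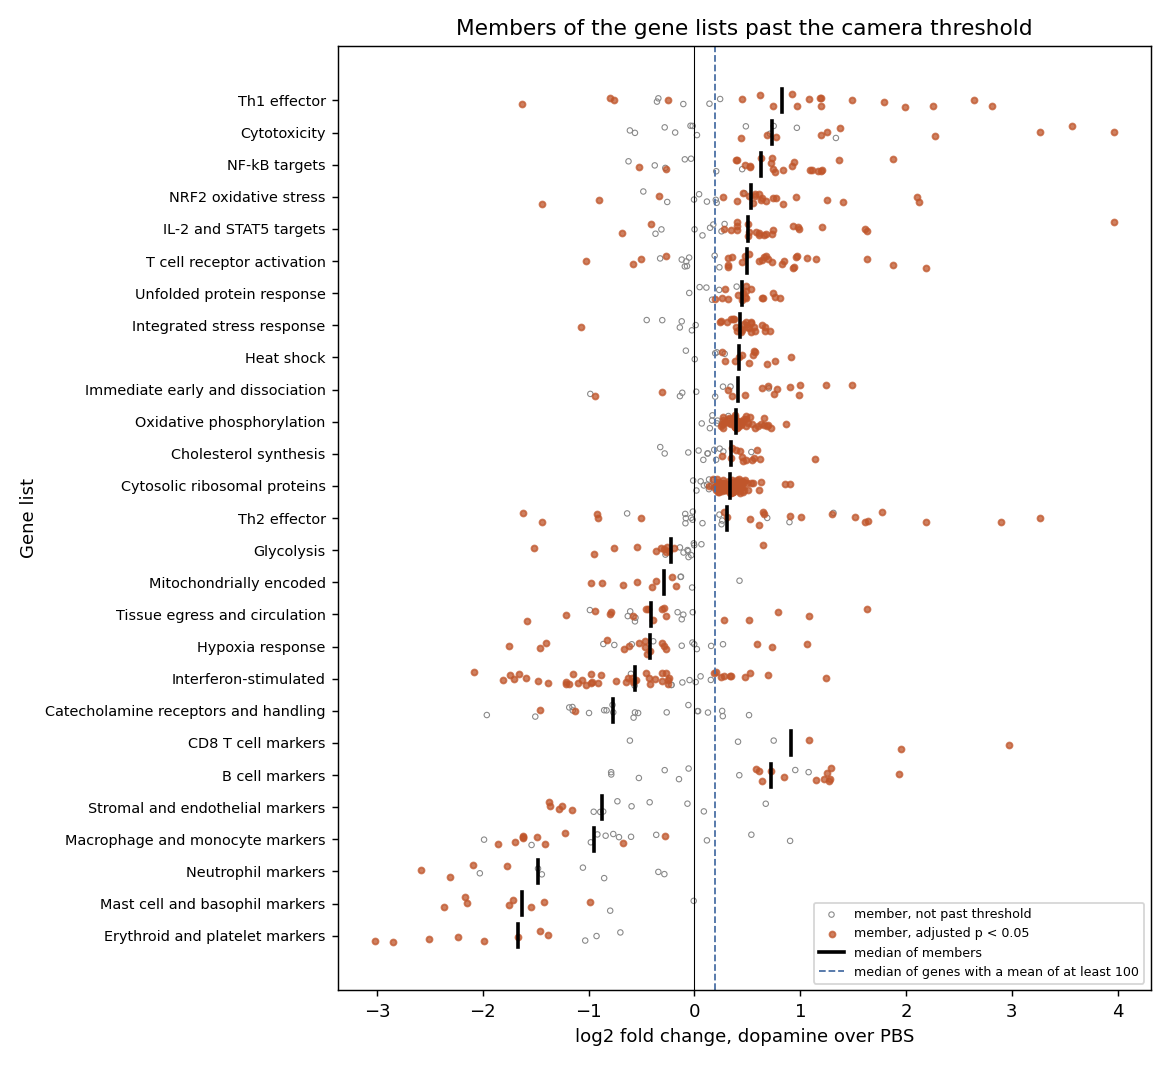
Log2 fold change (dopamine over PBS, horizontal axis) of each member of the gene lists that passed camera with the preset correlation, 1 list per line, with vertical jitter within a line. Filled points passed an adjusted p of 0.05 by limma, open points did not, the thick bar is the list median, and the dashed line at 0.198 is the median of genes with a mean of at least 100. Th1 effector genes have the highest median among the program lists (0.83), and the medians of oxidative phosphorylation (0.39) and ribosomal protein genes (0.34) compare with 0.198 for the dashed line.

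Transcripts known from other blood and spleen cells also differed between the groups. Mast cell and basophil markers fell: 8 of 10 lower and 0 higher by limma (8 and 0 adjusted over the list alone), with Cpa3 from 765 ± 120 to 235 ± 61.7. Erythroid and platelet markers fell: 8 of 11 lower and 0 higher by limma (10 and 0 adjusted over the list alone), with Pf4 from 537 ± 18.6 to 194 ± 6.85. Of 22 macrophage and monocyte markers, 10 fell and 0 rose by limma (11 and 0 adjusted over the list alone), with Lyz2 from 66.0 ± 2.03 to 23.3 ± 6.82. Of 11 neutrophil markers 4 fell and 0 rose by limma (6 and 0 adjusted over the list alone), with Mpo from 285 ± 25.4 to 66.4 ± 8.71. Of 14 stromal and endothelial markers 5 fell and 0 rose by limma (5 and 0 adjusted over the list alone). Only 2 stromal, 1 neutrophil, 9 macrophage and 5 erythroid or platelet markers had a mean of at least 20, and genes below that mean were lower in general, with a median log2 fold change of -0.485 at a mean of 5 to 20 and -0.562 under 5. The list medians were -0.876, -1.478, -0.948 and -1.663. B cell markers rose: 12 of 21 higher and 0 lower by limma (14 and 0 adjusted over the list alone), with Ms4a1 from 27.2 ± 7.11 to 105 ± 8.52 and Cd79b from 48.5 ± 3.53 to 120 ± 7.84. In this order camera's adjusted p was 6.59e-11, 5.58e-12, 8.14e-05, 9.7e-04, 0.01 and 2.14e-06. With an estimated correlation the adjusted p was 0.231, 0.239, 0.239, 0.334, 0.239 and 0.239. Without PBS A, with fewer samples, the numbers that fell were 6 for macrophage, 1 for neutrophil and 1 for stromal markers, and 1 macrophage marker rose. Their medians stayed near those of all libraries: -0.973 against -0.948, -1.476 against -1.478 and -0.762 against -0.876.

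**Figure D3:**
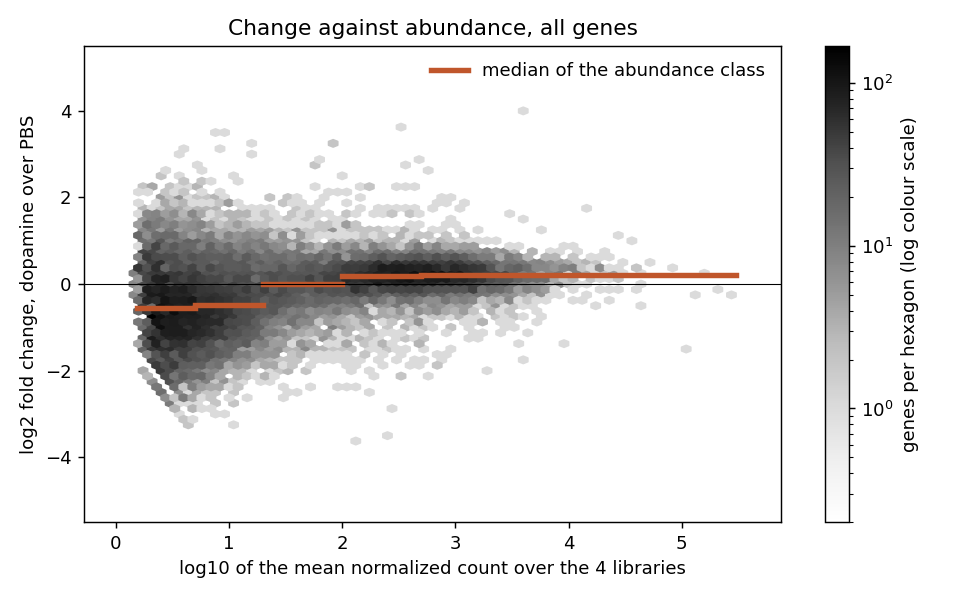
Log2 fold change (dopamine over PBS) of the 26207 genes against the log10 of their mean normalized count over the 4 libraries, with darker hexagons holding more genes. Orange lines are the median of each abundance class, which goes from -0.562 for the 8514 genes with a mean under 5 to 0.211 for the 4149 genes with a mean over 500.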

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

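The settings added after the data were seen are TMM scaling in limma, scaling or a background on genes with a mean of at least 100, the GC and length correction, edgeR with TMM and filterByExpr, and a replicate block on the numbers 2 and 3 of the column names, which recur in both groups. No label ties these numbers to shared cultures. Over the 8492 genes with a mean of at least 100, the deviations of same-numbered libraries from their group means had a correlation of 0.214. With the block 6999 genes (4627 higher), 21 program lists (15 higher) and 7 marker lists (2 higher) were called. Cd4 (adjusted p = 0.0207) and Cd3e (0.0391) then passed, as did the chemokine receptor (0.0247) and TGF-beta response (0.0119) lists, and the catecholamine list did not (0.0702). The planned filter on a mean of at least 1 was not run, since the lowest mean is 1.53 and it removes no gene.

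The number of changed genes, 5577, was 3261 in DESeq2, which tests fewer genes (12997), and 1424 with a change of at least 2-fold (326 higher). With each library left out it ranged from 2914 to 4299, from fewer samples. A lone library was then assumed to vary like the other group. In the other settings run without a block it stayed between 4519 and 5552. For program lists camera called 20 (14 higher), and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. With 4 libraries the setting with an estimated correlation had little power. Fry called 14: 13 of camera's 20, and tissue residency as higher (adjusted p = 0.0201). It did not call ribosomal proteins and cholesterol synthesis (adjusted p = 0.0567 each), glycolysis (0.0809) or interferon (0.0999). Nor did it call the egress, catecholamine or mitochondrial lists (0.0879 each). For markers of other cell types camera called 7 (2 higher). It called 2 among genes of at least 5 CPM and 2 on a background of genes with a mean of at least 100, where fewer lists keep 5 members, and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05, while fry called 5. The cell cycle list, with a median of 0.127 (adjusted p = 0.0687), passed as higher with a pseudocount of 0.1 (adjusted p = 0.0457) and without PBS B (0.0353). Its median turned to -0.068 when scaled on genes with a mean of at least 100 (adjusted p = 0.025) and to -0.064 with upper-quartile scaling in edgeR (adjusted p = 0.049), settings whose scaling lowers every fold change. Trbc2 turned from 0.235 to -0.084 after the GC and length correction, and the cause was not tested. No other named gene that was called changed sign in the settings run. DESeq2 ended the call of 12 of 177 tested named genes, leaving out PBS A that of 25 of 189, and limma with TMM scaling that of 0 of 189. Depth limits PBS A most, which holds 5717408 reads.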

Other observations

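The tests of a single scaling factor and of a lower basophil share and the split of the interferon list were chosen after their values were seen. So were Hdc, Ifng, Rmrp, Rpph1, Rn7sk, Gm10800 and Gm26917.

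Several lists did not pass camera. Of 50 cell cycle genes 9 rose and 3 fell (12 and 3 adjusted over the list alone), with Mki67 at -0.36 and Ccne1 at 0.43. Of 20 Treg genes 7 rose and 5 fell (adjusted p = 0.194), with Tnfrsf4 at 0.61 and Ctla4 at -1.02. Of 15 inhibitory receptor genes 7 rose and 4 fell (adjusted p = 0.151), with Havcr2 at 2.26 and Tox at -1.32. Of 24 TGF-beta response genes 8 rose and 4 fell (adjusted p = 0.111), with Rgs16 at 1.96. Of 16 Tfh genes 5 rose and 3 fell (adjusted p = 0.793), of 16 Th17 genes 2 rose and 2 fell (0.291), and of 23 Polycomb genes 7 rose and 3 fell (0.379). Of 26 p53 targets 5 rose and 2 fell (0.705), of 16 glucocorticoid response genes 3 rose and 3 fell (0.793), of 13 fatty acid synthesis genes 6 rose and 2 fell (0.111), and of 12 metallothionein and metal transport genes 2 rose and 0 fell by limma (0.847). Scaling on genes with a mean of at least 100 turned these counts: 2 cell cycle genes rose and 19 fell, 2 p53 targets rose and 7 fell, and 2 Polycomb genes rose and 6 fell. With upper-quartile scaling in edgeR 2 rose and 20 fell, 2 and 8, and 3 and 7. Under the first of these scalings 3 fatty acid synthesis genes rose and 4 fell, as did 4 and 5 Tfh, 1 and 2 metallothionein or metal transport, 2 and 5 glucocorticoid response, 1 and 5 Th17, 6 and 6 inhibitory receptor, 7 and 6 Treg and 7 and 6 TGF-beta response genes. Without PBS A 1 cell cycle gene rose and 1 fell, and 2 rose and 2 fell in each of the p53 and Polycomb lists. Lists that passed with a library left out were cell cycle without PBS B (adjusted p = 0.0353), and fatty acid synthesis (0.0396) and TGF-beta response (0.00518) without dopamine A. Median, mean or test differed in sign for the Tfh, metallothionein and TGF-beta lists. Among markers of other cells, 4 of 10 plasma cell genes rose (0.0801, but 0.018 without PBS A and 0.0217 when scaled on genes with a mean of at least 100, settings where 2 rose), 2 of 8 gamma-delta T cell genes rose (0.274), 2 of 15 dendritic cell genes rose and 2 fell (0.75), 1 of 10 natural killer genes rose and 3 fell (0.281, with 1 and 1 and a median going from -0.349 to 0.34 without PBS A), and 1 of 9 neuronal genes rose and 1 fell (0.459).

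Within the interferon list, of 10 guanylate-binding proteins and immunity-related GTPases 7 rose and 1 fell (median log2 fold change 0.22), against 3 and 36 of the other 46 (median -0.61). The split was made after the values were seen, so the Fisher's exact tests run on it carry no weight and their p-values are left out. Of the 10, 3 rose and 2 fell, with a median of 0.03, when scaled on genes with a mean of at least 100, and 3 rose and 1 fell without PBS A. Gzmb on chromosome 14 (from 56258838) and Mcpt8 (from 56082166) lie in the same stretch of protease genes and moved in opposite directions, by 3.96 and -2.15. Of transcripts made by RNA polymerase III, Rmrp went from 502 ± 8.63 to 1909 ± 224 and Rpph1 from 22082 ± 1159 to 44249 ± 5620. Rn7sk fell (log2 fold change -0.17, adjusted p = 0.00155), from 2.38% and 2.37% of reads to 1.95% and 1.85%. These RNAs lie outside the selection of poly(A) RNA by an mRNA kit. Their reads may reflect carry-over rather than transcript level, which was not tested. The predicted gene Gm10800 took 1.92% and 1.41% of reads in the PBS libraries and 0.624% and 0.421% in the dopamine libraries. Gm26917 went the other way, from 0.181% and 0.191% of reads with PBS to 0.348% and 0.393% with dopamine. The mitochondrial genome took 5.64% and 6.22% with PBS and 4.62% and 4.08% with dopamine.

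Genes of low abundance were lower in the dopamine libraries. The median log2 fold change of genes with a mean under 20 lay below that of genes over 500 by a difference of -0.73, which a single scaling factor per library cannot give. Without the shallow PBS library the difference was -0.68, which argues against that library as the whole source. Olfactory and vomeronasal receptor genes, 734 genes that T cells are not known to use, took 0.045% and 0.034% of reads with PBS and 0.020% and 0.015% with dopamine, a log2 ratio of -1.14. With 1778 to 4463 reads per library in total, these receptor genes are as a group of low abundance themselves. Their fall is thus part of the pattern rather than a separate test of its source. Diffuse reads, such as genomic DNA or unspliced RNA, may contribute to the pattern, and a response to dopamine stays open and was not tested.

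Transcripts of basophils, mast cells and platelets were lower in the dopamine libraries. A lower share of all cells other than T cells would lower B cell markers too, yet the 13 with a mean of at least 20 had a median log2 fold change of 1.15. The SD over these genes divided by the root of their number was 0.136. That value is a spread over genes of the same libraries and does not measure the error between libraries. A lower share of basophils or mast cells may contribute: 7 of the 8 members of that list with a mean of at least 20 fell, but Hdc, the histamine-forming enzyme, was at -0.01. Other cells can make Hdc, so a lower share and a change within the cells cannot be told apart. A response to dopamine is a further open explanation and was not tested.

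Granzymes, perforin and Ifng (log2 fold change 1.99) were higher in the dopamine libraries. CD8 T cells with both CD8 chains would raise Cd8a and Cd8b1 together, but Cd8b1 was at 0.41 with a 95% interval ending at 0.78, below the interval of Cd8a, which starts at 1.51. This rule was set beforehand, but the genes started at unlike levels, 73.5 for Cd8b1 and 27.5 for Cd8a with PBS. The same added cells could then give Cd8b1 the smaller log2 fold change. In normalized counts, though, Cd8a also rose by more, from 27.5 to 109, against 73.5 to 98.1 for Cd8b1. Unlike starting levels alone thus do not give the gap unless the added cells hold more Cd8a than Cd8b1, which was not tested. The interval of Cd8b1 also started at 0.044, on the side of a rise. The test therefore cannot decide, and CD8 T cells, cells with Cd8a alone, or gamma-delta T cells (Tcrg-C2 at 2.26), stay open. For natural killer cells, the members with a mean of at least 20 had a median of -0.99, below the bound set beforehand. All 3 (Tyrobp, Fcer1g and Kit) are also on the macrophage or mast cell lists, which fell. Klra7, the only member of the list called higher, went from 3.23 to 13.7 normalized counts (log2 fold change 1.80), under that mean. The bound was therefore wrong, and the explanation cannot be told apart from the others. A response of the Th2 cells to dopamine is the biological explanation the design gives, and it stays open.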
